A study of Mus musculus with 58 samples.

How the data were processed

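RNA-seq of primary mouse CD4+ T cells was analysed, in 58 libraries that fall into 15 groups: 3 genotypes in 5 states. Per the labels, wild-type (WT) cells were compared with cells that lost the miR-17~92 microRNA cluster through a Cre recombinase expressed under Cd4 control (KO), and with cells in which the same Cre removes a stop cassette in front of a miR-17~92 transgene in the Rosa26 locus (TG). Naive CD4+ T cells were isolated with a commercial kit from pooled lymph nodes and spleens of 10 mice of both sexes. They were collected untouched or after 24 h or 48 h on plates coated with anti-CD28 at 0.2 µg/ml and anti-CD3 at 0.25 µg/ml (very weak stimulus) or 0.5 µg/ml (weak stimulus), in medium with IL-2 at 50 U/ml. Each group held 4 libraries, except KO naive and WT naive cells with 3 (replicates 1, 2 and 4). Poly(A) RNA was extracted with DNase treatment, prepared with a stranded TruSeq kit and sequenced as single-end reads, per the labels' protocols.

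The values are counts of reads per gene that the authors deposited as whole-number tables, a full table and an intron table, with no normalization per the file headers and values. The submitters' processing notes name FastQC 0.11.5, STAR 2.5.2a, R 3.5 and edgeR 3.24.3 and the genome build mm10. The counting program, its annotation and its strand setting are not given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty. Low counts were also tested for signs of scaling: the log-likelihood of their frequencies gained at most 3.08 from any scaling factor tried, against at least 169 once the counts were scaled by 0.8 and rounded. All per-sample columns matched a library by its title. In 14.1% of values the intron count exceeded the full count, so the full table holds no intronic reads, and a fit with introns subtracted, considered before the data were examined, had no application. Full totals ran from 19.2 to 20.8 M counts per library (coefficient of variation 2.04%) and intron totals from 2.74 to 9.11 M. Gene IDs were matched to RefSeq symbols (23968 of 24028) or GENCODE symbols (7), and 53 stayed unnamed. Reads carry no molecular identifiers, so counting intervals and limits cover counting error only.

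Genes were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood F test, with TMM factors (0.939 to 1.06) and the filterByExpr filter, which kept 13709 genes; 4517 genes had 0 counts in every library. All 58 libraries entered a single fit with 1 coefficient per group and 43 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Comparisons were KO and TG against WT in each state, the same differences averaged over the 4 stimulated states, TG against KO averaged likewise, each WT stimulated state against WT naive cells, the weak against the very weak stimulus in WT cells, and the change of each genotype effect from the naive to the stimulated states. Averages over stimulated states treat 16 libraries per genotype as replicates, although libraries with the same number share a deviation. Counts were therefore also summed over the 4 stimulated states of each genotype and replicate number, and 4 sums were tested against 4. These sums are called pools below, although the labels do not state that equal numbers mark the same mice. Levels are counts-per-million (CPM) and carry the SD over libraries or pools. Log2 fold changes are edgeR estimates; a log-CPM scale with a prior count of 2 was used for list tests and scores.

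Named genes follow a rule fixed before the data were examined: the cluster's own transcripts, then for each of 6 comparisons the 8 largest rises and 8 largest falls among called genes with a group mean of at least 5 CPM, without unnamed models or antigen receptor segments, and up to 4 members of each gene list by smallest adjusted p, plus any member of the published target list. The 29 gene lists were also fixed before the data were examined, from textbook and published knowledge: miR-17~92 targets, early activation, naive state and quiescence, costimulatory and inhibitory receptors, calcineurin and NFAT, NF-kB, negative regulators of PI3K-AKT-mTOR, the BCL2 family, cell cycle, CDK inhibitors with the RB family, ribosome biogenesis, glycolysis, cholesterol biosynthesis, interferon response, TGF-beta signalling, Th1, Th2, Th17, T follicular helper and regulatory T cell genes, markers of B, CD8, NK, myeloid, erythroid and innate-like T cells, mitochondrially encoded genes, sex-linked genes, and heat shock and dissociation genes. None of the 13 mitochondrially encoded genes was measured. Lists were tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, and adjusted over lists within a comparison. Camera with an estimated correlation and fry were alternatives.

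Post-transcriptional change was measured as the KO or TG effect on exonic counts minus that on intronic counts, in 1 edgeR fit of both regions. For intronic work, 21 IDs with introns over 3 Mb, which held 22.7% of all intron counts, were left out. Seed sites of the miR-17, miR-18, miR-19 and miR-92 families were searched in the 3′ UTRs of 20365 genes of the GENCODE annotation of the same genome build, and genes with an 8mer site were compared with genes lacking any site of the 4 families. As a control, 100 other 7mers were searched the same way. Pool scores were compared by exact two-sided permutation tests of 4 against 4, which cannot give a p below 0.0286. These tests ignore the pairing of stimulated libraries by number that is described below. Splits that part all pairs are too few for a share under 0.05, so an exact permutation p of 0.0286 does not exclude chance.

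The labels give every group the same replicate numbers. Whether these pair the libraries was checked on correlations of deviations from group means. Between genotypes in 1 stimulated state, all 48 pairs correlated at 0.132 to 0.625, and between the 2 strengths at 1 time all 24 at 0.268 to 0.732, so numbers were taken to pair stimulated libraries. Between naive groups the 9 pairs ran from -0.0487 to 0.428. Their means were 0.201 (KO and WT), 0.166 (TG and WT) and 0.261 (TG and KO), against -0.101, -0.0554 and -0.0867 for different numbers. Whether numbers pair naive libraries was thus left open. Between naive and stimulated libraries the 40 pairs ran from -0.170 to 0.186, so numbers do not pair naive with stimulated libraries. At 48 h replicates 1 and 2 stood apart from replicates 3 and 4 most clearly in KO cells, so counts were also taken within each of these sets. Under the weak stimulus, variance between KO libraries of different sets was 4.47 to 6.83 times sampling noise, against 3.57 and 2.27 within sets. WT and TG cells were less clear. For WT it was 4.07 between replicates 1 and 2 and 3.04 between 2 and 4. For TG it was 3.32 between 1 and 2 and 2.35 between 1 and 4. No pair of libraries in a group differed by as little as sampling noise.

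Each fitting step was first tested on counts simulated from the real means with a known set of genes changed. In the KO against WT naive comparison, 34.3% of genes changed by log2 0.5 were recovered, 75.4% at 1 and 81.8% at 2. The average over stimulated states recovered 70.1%, 88.1% and 97.0%, and pool sums recovered 75.0%, 90.6% and 98.5%. Here each library was drawn independently, without the deviation that libraries of a pool share. These shares therefore do not test how the averages or pool sums handle that deviation. The comparison of the strengths recovered 0%, 79.3% and 98.3% when unpaired, using the 2 groups alone, and 78.3%, 87.9% and 100% when paired. That simulation used an assumed pool deviation and a dispersion set below that of the real fit, so its shares depend on these choices. For the exonic minus intronic effect in pool sums the shares were 7.46%, 70.1% and 97.0%. Unchanged genes made up 16 of 172 calls in the paired fit of the strengths and 11 of 137 in the KO naive comparison, more than the 1 in 20 aimed at. Alternatives planned before the data were examined were DESeq2 1.42.0, its size factors in edgeR, no filter, fits of the compared groups only, the replicate number as a block, leaving out each library, and others for the site and list tests. Pool sums, replicates 1 and 2 or 3 and 4 alone, the paired fit of the strengths, and the exclusion of overlapping genes were chosen after seeing the data.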

Results

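RNA was sequenced from CD4+ T helper cells of mice with a normal, deleted or added microRNA cluster, miR-17~92. The study's title names it as a mediator of costimulation, the signal through CD28 that T cells need beside that of their antigen receptor. WT cells, KO cells without the cluster and TG cells that express extra copies were each measured naive and after 24 h or 48 h under a very weak or a weak stimulus. KO and TG cells also carry Cre, which WT cells lack, so a comparison with WT does not on its own separate the cluster from Cre. The 58 libraries held 19.2 to 20.8 M counts each, so depth hardly differed between groups. Group means ranged from 19.4 M (TG, weak stimulus, 48 h) to 20.6 M (WT naive). The share of intronic counts was higher in naive cells, at 22.4% (KO), 23% (TG) and 25% (WT), than in stimulated groups, at 10.8% to 13%. Each group held 4 libraries, or 3 for KO naive and WT naive cells.

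The microRNA genes themselves followed the labels. Mir17, a hairpin of the cluster on chromosome 14 (115043671 to 115043754, mm10), had 2 counts in all 16 stimulated KO libraries against 57 in the 16 WT and 140 in the 16 TG libraries. The hairpin genes Mir18 (115043851 to 115043946), Mir19a (115044000 to 115044081) and Mir20a (115044157 to 115044263) were also lower in stimulated KO than in WT cells (edgeR, adjusted p = 5.44e-07, 4.46e-08 and 2.08e-08), as was Mir17 (7.40e-06). In TG naive cells Mir17 stood at 6.58 ± 2.54 CPM (SD, n = 4) and in WT naive cells at 0.165 ± 0.0820 (n = 3). After stimulation the Mir17 levels were 0.446 ± 0.266 in TG and 0.183 ± 0.136 CPM in WT cells (SD, 16 libraries each). In KO naive cells Mir17 had 3 counts over 3 libraries, against 10 in WT naive cells, too few for a call (edgeR, adjusted p = 0.996). The host gene row, Mir17hg (115044390 to 115046728), lies almost wholly beyond these hairpins and does not check the deletion. Its level after stimulation was 120 ± 9.17 CPM in KO against 39.6 ± 2.67 in WT pools (n = 4), a rise of log2 1.59 (edgeR, adjusted p = 2.82e-11).

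Further marks of the engineered alleles were also in place. Gt(ROSA)26Sor, the transcript of the Rosa26 locus on chromosome 6 (113067428 to 113077244) that received the transgene, had 0.767 ± 0.658 CPM in TG naive cells and 0.0641 ± 0.0610 in stimulated TG cells, against 6.31 ± 1.78 and 5.19 ± 1.38 in WT cells. Gh, the growth hormone gene on chromosome 11 (106300261 to 106303703) whose sequence is part of many Cre transgenes, had 32.7 ± 11.7 CPM in KO naive and 29.6 ± 10.5 in TG naive cells, and 0.262 ± 0.123 in WT naive cells. Intronic counts of Cd4 (chromosome 6, 124864693 to 124888247) were 646 ± 136 CPM in KO, 521 ± 42 in TG and 115 ± 10.7 in WT naive cells, and 81.0 ± 30.4, 53.3 ± 8.51 and 21.2 ± 3.55 after stimulation. Gh set every KO and TG library apart from all WT libraries, and Gt(ROSA)26Sor set every TG library apart from all others. Mir17 counts were too few to sort single libraries: KO naive replicate 2 and WT naive replicate 2 had 3 counts each.

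**Figure D1:**
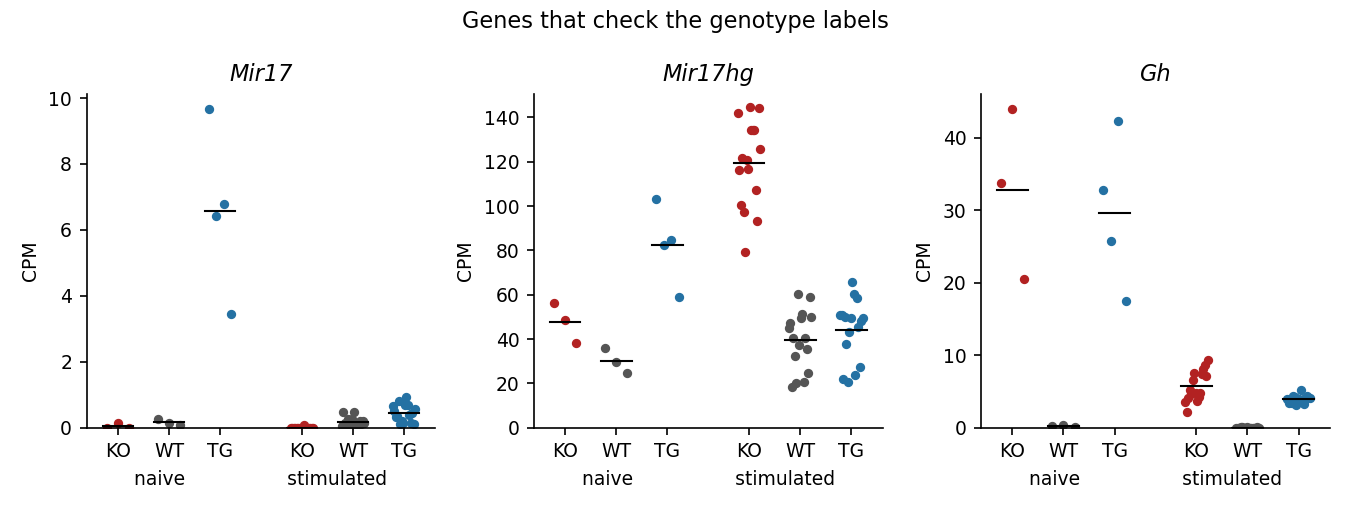
CPM of Mir17, Mir17hg and Gh in each library, by genotype and by naive or stimulated state, with horizontal lines at the mean of each genotype. Gh was high in KO and TG and near 0 in WT libraries, and Mir17 was highest in TG naive libraries.

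Stimulated and naive WT cells differed in most genes. After 24 h of the weak stimulus the amino acid enzyme Bcat1 stood at 284 ± 28.4 CPM (n = 4) against 1.59 ± 0.323 (n = 3) in naive cells, and the adenylate kinase Ak4 at 40.2 ± 15.5 against 0.241 ± 0.192. The other large rises started from 1 to 3 naive counts: Bdh2 594-fold (95% counting interval 106 to 23496), Cth 454-fold (81.2 to 17977), Adh4 389-fold (69.5 to 15391), Etv4 207-fold (70.5 to 1005), Arhgdig 169-fold (46.6 to 1402) and Lancl3 143-fold (48.6 to 695). Among genes without counts in this state, C1qc was at least 497-fold lower, C1qb at least 481-fold, Fcna and Mrc1 at least 373-fold, Marchf1 at least 204-fold and Hpgd at least 149-fold, against a floor of 3 counts over the group. The near-identical heat shock genes Hspa1a and Hspa1b were 1119-fold and 1018-fold lower and varied widely in WT naive cells (169 to 1510 CPM for Hspa1a).

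Of 31 measured cell cycle genes, 30 rose, among them the nucleotide reductase subunit Rrm1 (log2 4.16) and the replication helicase subunits Mcm7 (3.16), Mcm5 (3.96) and Mcm3 (3.80). All 28 ribosome biogenesis genes rose (Noc4l 2.55, Nop2 2.37), as did 15 of 20 glycolysis genes (Tpi1 4.26, Pgam1 3.52; 1 fell) and 21 of 23 cholesterol biosynthesis genes (Cyp51 3.11, Idi1 3.51; 1 fell). Early activation genes rose in 17 of 25 and fell in 4, with the interleukin-2 receptor chain Il2ra at 4.42 and the transcription factor Irf4 at 4.25; costimulatory and inhibitory receptors rose in 14 of 20 and fell in 3 (Cd200 4.58, Pdcd1 4.35). Naive state and quiescence genes fell in 21 of 25 and rose in 2 (Rasgrp2 -6.03, Tcf7 -2.88), interferon response genes fell in 21 of 25 (Oas2 -7.03, Irf9 -1.52), and TGF-beta signalling genes fell in 12 of 18 and rose in 4 (Smad7 -4.67, Tgfbr2 -3.00). Markers of other cells fell together: all 15 B cell genes, 7 of 8 CD8 genes, 11 of 13 NK genes, 21 of 22 myeloid genes (Csf1r -8.66, Lyz2 -6.59) and all 9 erythroid genes. Adjusted over the list alone the same numbers were called, except 8 CD8 and 12 NK genes that fell.

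Those lists differed from all other genes with camera adjusted p between 2.39e-18 (cell cycle) and 0.0162 (CD8). With an estimated correlation the cell cycle call held (adjusted p = 0.00370) and the others did not: the next smallest values were naive state and myeloid (adjusted p = 0.0713 each, estimated correlation) and the receptors (0.0901). In all, edgeR called 10615 of 13709 genes at this state (5042 higher, 5573 lower), and 10458, 10649 and 10727 after the very weak stimulus for 24 h and 48 h and the weak stimulus for 48 h. Naive cells were unpaired, uncultured and richer in markers of other cells, so culture, IL-2 and their loss cannot be told from the stimulus.

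The 2 stimulus strengths, which differ only in their anti-CD3 dose, were hard to tell apart in WT cells. With all libraries in the fit, edgeR called 0 genes at 24 h and 0 at 48 h (unadjusted p under 0.05 in 280 and 352 genes; 0 and 0 by DESeq2, unadjusted 290 and 365). Replicate numbers pair these libraries, and a fit of the 2 groups with pairs, chosen after seeing the data, called 414 genes at 24 h (166 higher, 248 lower under the weak stimulus) and 728 at 48 h (476 higher, 252 lower). Of these, 146 genes were called at both times, all in the same direction, and 21 and 30 changed at least 2-fold. In that fit the T cell cytokine genes Il2 (log2 1.55 and 1.51 at 24 h and 48 h) and Il3 (2.0 and 1.82) and the fatty acid enzyme Acsl6 (1.24 and 1.42) were higher under the weak stimulus at both times, and Ccn1 (1.57) at 24 h and Csf2 (1.65) at 48 h. These genes were picked after their values were seen. Of the lists, ribosome biogenesis stood above other genes at 24 h (median log2 0.116, camera adjusted p = 1.52e-05) with 0 of 28 members called; the adjusted p was 0.898 with an estimated correlation. With the replicate block early activation (adjusted p = 0.0161, up), B cell (0.0160, down) and NK cell markers (0.0498, up) passed too, but none did with an estimated correlation (0.898 each).

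In the naive state, KO cells differed from WT in few genes and TG cells in many. KO naive cells differed from WT in 5 genes by edgeR (unadjusted 651; DESeq2 7). Besides Gh (log2 6.94), Adk, which encodes adenosine kinase, was higher (82.3 ± 11.5 against 45.6 ± 8.86 CPM, n = 3 each; log2 0.85, SE 0.164, adjusted p = 0.0136) and the tetraspanin gene Tspan9 lower (13.8 ± 1.30 against 33.5 ± 3.92 CPM; log2 -1.28, SE 0.238, adjusted p = 0.00926). Pmel (-2.62) and Ccdc102a (-1.75) complete the 5; their levels lay under the naming minimum and they were picked after their values were seen. Cell cycle genes lay lower as a list (0 of 31 called, 4 lower when adjusted over the list alone; camera adjusted p = 6.04e-04) and cholesterol genes higher (0 of 23 called; 6.04e-04), both lost with an estimated correlation (adjusted p = 0.969 each). The count was 2 without KO naive replicate 1 and 20 without KO naive replicate 2.

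In TG naive cells edgeR called 1074 genes, 594 higher and 480 lower. After Gh, Mir18 (log2 5.36) and Mir17 (5.28), the largest rise was that of Adgrg5, an adhesion receptor (105 ± 16.6 CPM, n = 4, against 8.73 ± 3.02, n = 3; log2 3.59, SE 0.279, adjusted p = 1.80e-13). Ier5l (3.10), Adamtsl2 (2.67), Ccdc102a (2.60) and the growth factor gene Bmp7 (2.57) followed. After Gt(ROSA)26Sor (-3.03), large falls were those of Drc1 (-2.40), Nacc2 (-2.20), the cytoskeletal gene Pdlim4 (-2.10), Galnt9 (-1.93), Dnajc6 (-1.81) and Map3k9 (-1.68). Inhibitory and costimulatory receptors rose in 4 of 20 with 0 falling (Pdcd1 1.28, Cd160 1.41, Ctla4 0.75, Tigit 0.79), cell cycle genes in 5 of 31 with 0 falling (Mcm5 0.63, Top2a 0.70), and regulatory T cell genes in 4 of 14 with 0 falling (Nrp1 0.92, Ikzf2 0.90). Ribosome biogenesis genes fell in 4 of 28 (Utp20 -0.58, Polr1a -0.41) and cholesterol genes in 3 of 23 (Sqle -0.56). Of 30 published targets, 1 rose (Rora 1.29) and 2 fell (Rcan3 -0.90, Zbtb4 -0.64), with no shift of the list (camera adjusted p = 0.238). The survival gene Bcl2 fell by 0.89, and 3 of 18 heat shock genes fell (Hspa1a -1.62).

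Adjusted over the list alone, 6 receptors rose and 1 fell, 7 cell cycle genes rose and 1 fell, and the other naive lists named kept their counts, except 4 heat shock genes that fell. The camera calls for receptors (adjusted p = 0.0201), cell cycle (5.13e-04), regulatory T cell (0.00265), ribosome biogenesis (0.00148) and cholesterol genes (0.0201) were lost with an estimated correlation, where the adjusted p values were 0.254, 0.512, 0.0917, 0.900 and 0.936. The genotype effect itself differed between stimulated and naive cells for 23 genes in KO and 847 in TG cells. Without WT naive replicate 4 the naive TG count fell to 526 and the TG number of 847 to 387, and without KO naive replicate 4 the KO number of 23 fell to 1.

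**Figure D2:**
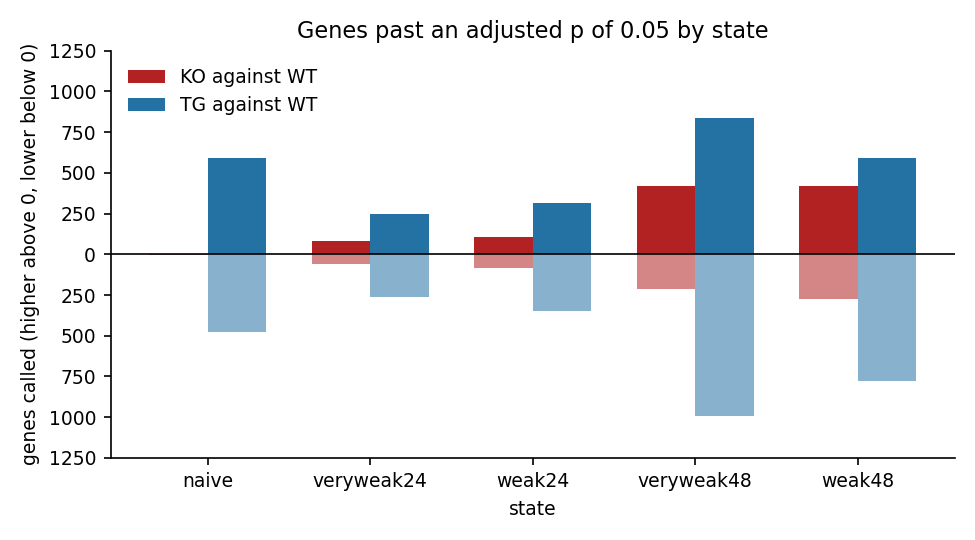
Number of genes called by edgeR (adjusted p under 0.05) in KO and TG against WT in each state, with higher genes in full colour and lower genes in paler bars below 0. TG counts lay above KO counts in every state, from 1074 against 5 genes in naive cells to 1826 against 635 after 48 h of the very weak stimulus.

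After stimulation, KO cells differed from WT in 145 and 635 genes (very weak stimulus, 24 h and 48 h) and in 192 and 691 genes (weak stimulus, 24 h and 48 h). TG cells differed in 511, 1826, 660 and 1366 genes. With the replicate block the KO counts were 350, 1145, 436 and 1193, and the TG counts at 24 h were 920 and 1162. Single libraries weighed on these numbers: without 1 library KO ran from 68 (without KO replicate 4) to 223 (without KO replicate 1) and from 327 (without WT replicate 2) to 1281 (without KO replicate 3) under the very weak stimulus, and fell to 110 (without WT replicate 1) and 355 (without WT replicate 2) under the weak stimulus. TG fell to 269 (without TG replicate 1) at 24 h of the very weak stimulus and to 292 and 812 (each without TG replicate 2) at 24 h and 48 h of the weak stimulus. In the states taken singly, 68 genes were called the same way in all 4 in KO cells and 224 in TG cells, of 988 and 2512 called in any. Within replicates 1 and 2 alone, which stood apart from 3 and 4 at 48 h, the KO counts in the same order were 9, 392, 34 and 367. Within replicates 3 and 4 the values at 48 h were 217 and 246, and 79 at 24 h of the weak stimulus.

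Averaged over the stimulated states, single interferon-inducible genes were higher in KO cells, while their list was not called (camera adjusted p = 0.327). Large rises were those of Gh (log2 8.38), Ifi214 (34.5 ± 14 against 10.7 ± 1.93 CPM, n = 4 pools; log2 1.60, SE 0.256, adjusted p = 4.62e-06), Mir17hg, Ifit3b (1.5), Ifi209 (1.5), Ifi208 (1.35) and Ifit3 (1.31). Ifi208, Ifi209 and Ifi214, and likewise Ifit3 and Ifit3b, are similar copies, among which reads could be split. The falls were led by Ajuba, a scaffold protein gene (1.99 ± 0.346 against 10.1 ± 2.64 CPM; log2 -2.22, SE 0.155, adjusted p = 1.19e-15), transglutaminase Tgm2 (-2.12), the AP-1 factor Batf3 (-1.72), Crabp2 (-1.71), Tbkbp1 (-1.5), Pros1 (-1.45), the retinol transporter Stra6 (-1.43) and Ifng, interferon-gamma (-1.42). In all 3349 of 13709 genes were called, 1786 higher and 1563 lower, 180 of them at least 2-fold. The average treats 16 libraries as independent; over 4 pools against 4, 805 genes were called, and Ifi208 (adjusted p = 0.102), Ifit3 (0.0697), Tgm2 (0.159), Batf3 (0.0589), Stra6 (0.207) and Ifng (0.141) were not. With pools also paired by number 2630 genes were called, these 6 among them (adjusted p = 6.34e-04 for Tgm2 to 0.0383 for Ifit3). Within replicates 1 and 2 the average called 2055 genes and within 3 and 4 it called 2430.

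Published targets of the cluster moved up in stimulated KO cells: 14 of 30 rose and 0 fell (15 and 1 adjusted over the list alone; median log2 0.14, camera adjusted p = 1.23e-06, and adjusted p = 0.103 with an estimated correlation). The largest rises were those of Zbtb4 (1.04), Hbp1 (0.87), Rora (0.71), Rcan3 (0.63) and the TGF-beta receptor Tgfbr2 (0.60), and the pro-apoptotic gene Bcl2l11, which encodes BIM, rose by 0.59 (124 ± 14.5 against 82.5 ± 7.46 CPM). The phosphatase gene Phlpp2 rose by 0.40; over pools it was at adjusted p = 0.0577, and at 0.00560 with pools also paired by number. The targets Cdkn1a (0.08, adjusted p = 0.786) and Socs1 (-0.14, 0.512) were not called. This list comes from published work in other samples.

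Besides the targets, 6 lists shifted by camera in stimulated KO cells. Ribosome biogenesis genes fell in 12 of 28 with 0 rising (Noc4l -0.34, Rrp12 -0.28; camera adjusted p = 1.78e-06), glycolysis genes in 7 of 20 with 0 rising (Slc2a3 -0.63, Hk2 -0.42; adjusted p = 0.0125), Th1 genes in 8 of 13 with 1 rising (the Th1 regulator Tbx21 -1.08, Il18r1 0.76; 0.00157), Th2 genes in 6 of 12 with 0 rising (Il4ra -0.58, Ccr8 -0.80; 5.92e-05), and early activation genes in 8 of 25 with 1 rising (Irf8 -1.22, Il2ra -0.49, Cd69 0.54; 0.00886). CDK inhibitor and RB family genes rose in 4 of 11 with 0 falling (Rbl2 0.51, Btg2 0.46; 0.00886). All 6 calls ended with an estimated correlation (adjusted p = 0.724 for glycolysis, 0.585 for each of the others), and fry did not call glycolysis (adjusted p = 0.0687). Adjusted over the list alone the falls were 12, 8, 10, 7 and 10, with 2 Th1 rises, and the CDK inhibitor rises were 6. Interferon response genes rose in 4 of 25 with 0 falling (median 0.486, camera adjusted p = 0.327; adjusted p = 0.0443 over pools and 0.851 with an estimated correlation), with a median of 0.613 within replicates 1 and 2 and -0.410 within 3 and 4.

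The remaining KO lists did not shift by camera. Members rising and falling were 6 and 2 of 25 for the naive state (Klf2 0.87), 4 and 1 of 20 for costimulatory and inhibitory receptors, 3 and 1 of 19 for calcineurin and NFAT, 5 and 2 of 24 for NF-kB, 4 and 2 of 20 for PI3K-AKT-mTOR regulators, 1 and 1 of 17 for the BCL2 family, 5 and 6 of 31 for cell cycle, and 2 and 0 of 23 for cholesterol biosynthesis. They were 3 and 4 of 18 for TGF-beta signalling, 3 and 2 of 11 for Th17, 4 and 2 of 14 for T follicular helper, 1 and 3 of 14 for regulatory T cell genes, and 0 and 1 of 18 for heat shock. Markers of other cells rose and fell in 0 and 0 of 15 (B), 1 and 2 of 8 (CD8), 0 and 3 of 13 (NK), 2 and 0 of 22 (myeloid), 0 and 0 of 9 (erythroid) and 1 and 2 of 5 (innate-like). Of 5 sex-linked genes, 2 Y-linked genes rose (Ddx3y 0.81, Kdm5d 0.64); they were not called over pools (adjusted p = 0.318 and 0.406), nor over paired pools (0.123 and 0.208). Stimulated replicate 3 libraries stood apart here: Xist, which is expressed in female cells, had 45.1 to 97.8 CPM in KO, 433 to 587 in TG and 647 to 1050 in WT, and Ddx3y had 63.0 to 77.9, 18.4 to 25.5 and 6.54 to 7.95. The sexes were thus mixed differently, which is a limit of stimulated comparisons of KO or TG with WT that include replicate 3, also of those within replicates 3 and 4. With the replicate block the NK and sex-linked lists passed (adjusted p = 0.0412 each), but not with an estimated correlation (0.585 each) or over pools (0.163 and 0.316). The list mean and median differed in sign for cell cycle, the BCL2 family and T follicular helper genes.

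In stimulated TG cells, type 2 cytokine genes rose and interferon-inducible genes fell. Il13 stood at 26.7 ± 33.3 CPM against 1.26 ± 0.764 (n = 4 pools; log2 3.82, SE 0.373, adjusted p = 3.93e-11) and Il4 at 10.3 ± 3.62 against 0.997 ± 0.533 (3.38, SE 0.264, 2.36e-14). Stra6 (3.08), Batf3 (2.89), Rnd3 (2.86), Il10 (2.83), Il24 (2.83) and the activin subunit gene Inhba (2.68) were also higher. Besides Gt(ROSA)26Sor (-6.23), the largest falls were those of Ifi214 (2.59 ± 0.757 against 10.7 ± 1.93 CPM; -2.85, SE 0.327, 1.32e-09), Ifi208 (-2.82), Ifi44 (-2.50), the antiviral genes Mx2 (-2.31) and Oasl2 (-2.28), Ifi209 (-2.22) and Phf11a (-2.12). EdgeR called 4634 genes, 2212 higher and 2422 lower, 498 at least 2-fold. Over 4 pools against 4 it called 1840, and Il24 (adjusted p = 0.0954) and Oasl2 (0.0562) were not called. With pools also paired by number it called 3972, with Il24 (adjusted p = 3.43e-04) and Oasl2 (0.0213). Within replicates 1 and 2 the average called 3378 genes, and 2771 within 3 and 4.

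Th2 genes rose in 11 of 12 (the same number adjusted over the list alone; median log2 2.10, camera adjusted p = 1.72e-13), with the hypoxia factor Epas1 at 2.54 and the chemokine receptor Ccr8 at 1.49, and this call held with an estimated correlation (adjusted p = 0.0351). Interferon response genes fell in 20 of 25 with 0 rising (21 adjusted over the list alone; median -1.23, camera adjusted p = 7.55e-07, and adjusted p = 0.585 with an estimated correlation); their median was -1.38 within replicates 1 and 2 and -0.857 within 3 and 4. Published targets fell in 14 of 30 and rose in 2 (14 and 3 adjusted over the list alone; median -0.14, camera adjusted p = 0.00397, and adjusted p = 0.508 with an estimated correlation), with Zbtb4 at -0.73, Hbp1 at -0.64, Rcan3 at -0.56 and Fnip1 at -0.51, and Socs1 at 0.38. Ribosome biogenesis genes rose in 9 of 28 with 0 falling (Rrp9 0.21; camera adjusted p = 0.00549, and adjusted p = 0.752 with an estimated correlation). T follicular helper genes fell in 8 of 14 and rose in 2 (Icos -0.46, Il21 2.61; camera adjusted p = 0.0430, adjusted p = 0.508 with an estimated correlation, and 0.0621 over pools).

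No other TG list shifted by camera. Early activation genes rose in 7 of 25 and fell in 4 (Cd44 1.03, Il2ra 0.64, Icos -0.46), Th1 genes rose in 6 of 13 and fell in 3 (Ifng 2.24, Cxcr3 1.30, Il18r1 -1.49), and Th17 genes rose in 5 of 11 and fell in 1 (Ahr 1.11). Naive state genes rose in 4 and fell in 11 of 25 (Satb1 0.93, Il6ra -0.76), receptors in 3 and 8 of 20 (Tigit 0.85, Btla -0.60), calcineurin and NFAT genes in 3 and 5 of 19, NF-kB genes in 2 and 7 of 24, PI3K-AKT-mTOR regulators in 3 and 5 of 20, the BCL2 family in 3 and 3 of 17 (Bcl2l11 -0.33), cell cycle genes in 9 and 6 of 31, and CDK inhibitors in 0 and 5 of 11. The same numbers were 2 and 3 of 20 for glycolysis, 1 and 5 of 23 for cholesterol, 6 and 2 of 18 for TGF-beta signalling, 5 and 2 of 14 for regulatory T cell genes (Foxp3 -1.18) and 7 and 0 of 18 for heat shock. Markers of other cells rose and fell in 2 and 0 of 15 (B), 2 and 1 of 8 (CD8), 2 and 1 of 13 (NK), 1 and 2 of 22 (myeloid), 0 and 0 of 9 (erythroid), 1 and 1 of 5 (innate-like) and 0 and 0 of 5 (sex-linked). With the replicate block the naive state (adjusted p = 0.0419, down), CDK inhibitor (0.0432, down), Th1 (0.0432, up), Th17 (0.0315, up) and heat shock lists (0.0475, up) passed. They did not pass with an estimated correlation (adjusted p = 0.585, 0.585, 0.780, 0.585 and 0.780) or over pools (0.0777, 0.131, 0.287, 0.175 and 0.147). Median and mean differed in sign for calcineurin and NFAT genes, and the test differed from both for PI3K-AKT-mTOR regulators and sex-linked genes.

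**Figure D3:**
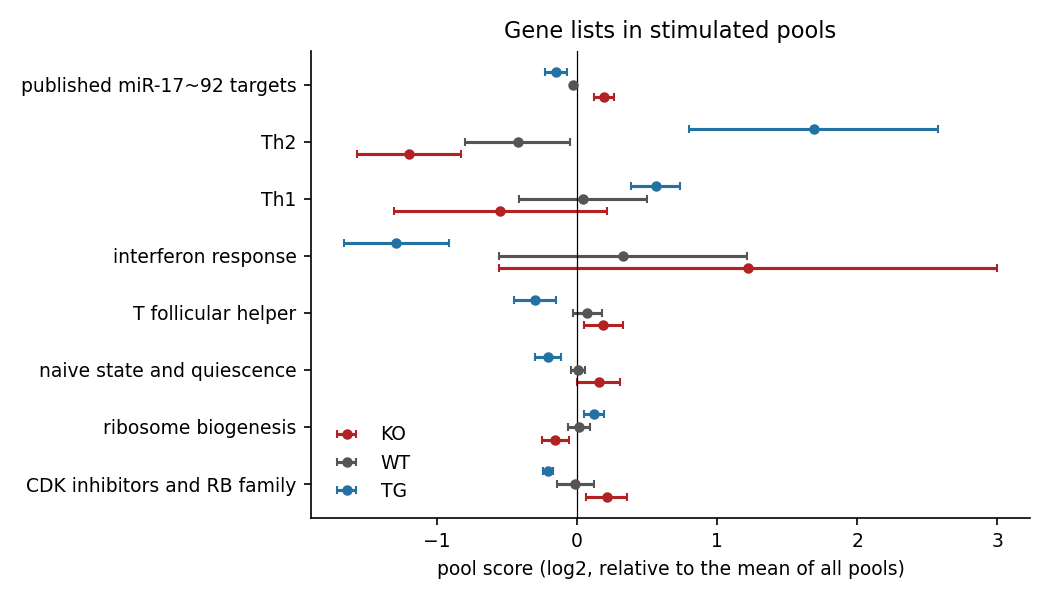
Pool scores of selected gene lists for the KO, WT and TG pools over the stimulated states. A score is the median log2 CPM of the list relative to the mean of all pools, less the same median of all other genes. Points and bars show the mean and SD of 4 pools. Th2 scores averaged 1.69 in TG, -0.422 in WT and -1.19 in KO pools, and interferon scores spread from -0.358 to 3.19 between KO pools.

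The KO and TG effects mirrored each other. Of 2178 genes called in both averages, 2127 (97.7%) moved in opposite directions, 1148 higher in KO and lower in TG and 979 the reverse, and 51 moved the same way. Independent lists of these sizes would share 568 genes in opposite and 564 in the same direction. Both comparisons use the same WT libraries, which alone gave a simulated correlation of 0.50 and covariance of 0.0269 over 20 rounds, against -0.51 and -0.0915 observed across genes in pool sums. With KO set against WT replicates 1 and 2 and TG against 3 and 4, 1296 genes moved in opposite directions and 15 the same way. With the WT sets exchanged the numbers were 836 and 13. KO and TG kept all replicates here, so any difference between the WT sets enters with opposite signs. These split counts are therefore no independent check of the opposite directions. TG compared directly with KO cells differed in 7957 genes, 3881 higher and 4076 lower. Over pools the counts were 491 opposite and 6 the same, and 1658 and 33 with pools also paired by number. In naive cells 4 genes were called in both, 3 of them in opposite directions.

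**Figure D4:**
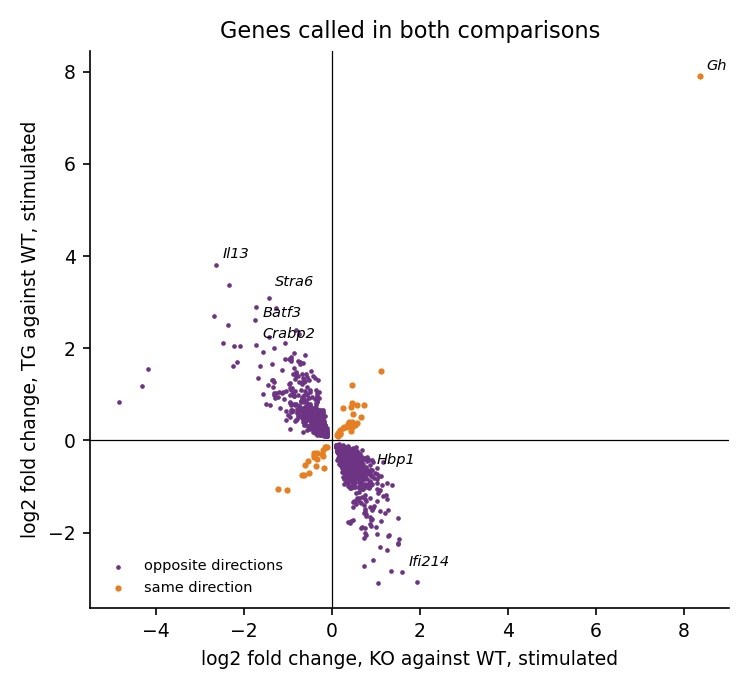
Log2 fold change in TG (vertical axis) against KO (horizontal axis), both against WT and averaged over the stimulated states, for genes called in both. Of 2178 genes, 2127 lay in the upper left or lower right.

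Transcripts with seed matches lay higher in KO and, less clearly, lower in TG cells. In stimulated KO cells the 1665 genes with an 8mer site lay 0.112 above the 7063 genes without any site in median log2 (camera adjusted p = 3.56e-09; p = 9.12e-04 with an estimated correlation), with 0.155 for the miR-17, 0.0783 for the miR-18, 0.108 for the miR-19 and 0.131 for the miR-92 family. In TG cells the difference was -0.0653 (camera adjusted p = 0.00280, and p = 0.0814 with an estimated correlation), with -0.104, -0.0226, -0.0548 and -0.0839 for the families. The TG value for miR-18 was not called (camera adjusted p = 0.316; 49 of 100 control 7mers were as large), and those for miR-19 and miR-92 did not pass with an estimated correlation (p = 0.116 and 0.0965). Pool scores of any family averaged 0.101 ± 0.0707 in KO, -0.0157 ± 0.0107 in WT and -0.0847 ± 0.0479 in TG (SD, n = 4); the exact permutation p was 0.0571 for KO against WT, 0.114 for TG against WT and 0.0286 for TG against KO, the smallest possible. For miR-17 sites it was 0.0286 in all 3 comparisons. None of these permutation tests keeps pairs. For miR-18 sites the exact permutation p was 0.143 (KO against WT), 0.743 (TG against WT) and 0.0571 (TG against KO). In the same order it was 0.0286, 0.114 and 0.0286 for miR-19 sites, and 0.0571, 0.0286 and 0.0286 for miR-92 sites. Of 100 control 7mers, 1 gave a difference as large in size in KO and 12 in TG; the controls ran from -0.188 to 0.0800 and from -0.138 to 0.515, on a median of 82 genes each.

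**Figure D5:**
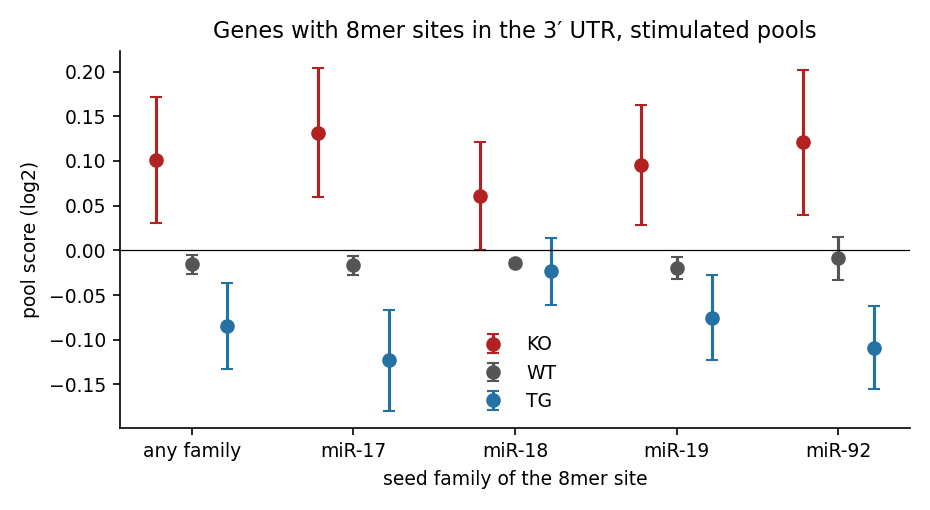
Median log2 CPM of genes with an 8mer site relative to genes without a site, per pool over the stimulated states, for each microRNA family, with the mean and SD of 4 pools. KO pools ran from -0.00247 to 0.151 for any family and TG pools from -0.116 to -0.0148.

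In intronic counts, a measure closer to transcription, the site difference was -0.00892 in KO and 0.00512 in TG. Exonic minus intronic scores of pools differed by 0.116 in KO (exact permutation p = 0.0286, the smallest possible, with pairs ignored). In TG they differed by -0.0742 (exact permutation p = 0.2). Exonic change beyond intronic change was called for 260 of 10803 genes in KO (183 higher, 77 lower) and 395 in TG (179 higher, 216 lower). Of 30 published targets, 8 were higher in KO with 0 lower: Zbtb4 (0.88), Hbp1 (0.64), Tgfbr2 (0.58), E2f1 (0.43), Phlpp2 (0.42), Rcan3 (0.38), Rbl2 (0.33) and Fnip1 (0.30). In TG 4 were lower with 0 higher: Phlpp2 (-0.41), Rbl2 (-0.36), Tgfbr2 (-0.30) and E2f1 (-0.28). Over unpaired pools these targets were not called, with adjusted p = 0.0518 to 0.635 in KO and 0.112 to 0.521 in TG. Among them Hbp1, Phlpp2, Rcan3, Rbl2 and Fnip1 overlap another gene, whose reads the counts do not separate. List medians were 0.16 in KO, with 23 of 30 above 0, and -0.12 in TG, with 8 above 0. Over pools the counts were 46 and 31 genes, or 401 and 526 with pools also paired by number, and among genes that overlap no other gene they were 104 and 120.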

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

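The test of the WT naive library that stands apart was chosen after the counts were seen, as was the use of pools; the remaining tests in this part were planned. Stimulation and the naive state gave different genotype effects, mostly in TG cells. The TG effect differed between stimulated and naive cells for 847 genes, with estimates of opposite sign in 639, larger in naive cells in 165 and larger in stimulated cells in 43. Some engineered or naive-cell rises shrank: the difference (stimulated minus naive, log2) was -3.80 for Mir18, -4.08 for Mir17, -1.29 for Adgrg5, -2.42 for Ier5l and -1.26 for Bmp7. Adamtsl2 went from 2.67 in naive cells to -0.62 after stimulation, where it was not called (adjusted p = 0.405; difference -3.29). Rises seen after stimulation and not in naive cells were those of Batf3 (difference 2.93) and Rnd3 (2.98), and falls seen only after stimulation were those of Ifi214 (-2.88) and Ifi209 (-2.27). The fall of Gt(ROSA)26Sor was larger after stimulation (-3.20), whereas Nacc2 fell less (1.43). The KO effect differed for 23 genes, 18 with opposite signs, 2 larger naive and 3 larger stimulated; among named genes only Adk was among them (-0.79, SE 0.178, adjusted p = 0.0429), with a rise of 0.85 in naive cells and 0.06 after stimulation. The TG number was 387 without WT naive replicate 4, 493 without WT naive replicate 2 and 543 without TG naive replicate 4. The KO number was 1 without KO naive replicate 4 and 111 without KO naive replicate 2.

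In TG naive cells 1074 genes differed from WT, and in KO naive cells 5. KO naive cells held fewer libraries, which is argued against as the whole cause. Without 1 TG naive library, the same number as in KO naive cells, the TG naive count was still 636 to 1195. A single WT library that stands apart is argued against as the whole cause: the count was 526 without WT naive replicate 4, the lowest value when any 1 library was left out. Other cell types in the naive preparations cannot be told apart from the genotype, because their 6 marker lists moved in both directions without a call, from a median log2 of -0.825 (erythroid) to 0.113 (B cell). Whether the transgene itself makes naive cells differ more than the deletion stays open, as a difference that the design names and that was not tested on its own.

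Single samples stood far from the rest of their group in 10 of 117 groups checked, where chance alone gives about 1 in 20 groups. The measure is the gap to the nearest other sample as a share of the whole range. Interferon-inducible genes were highest in WT pool 1, with Ifit3b at 4.93 CPM against 1.67 to 1.98 in the other pools (gap 0.906) and Ifit3 at 14.1 against 4.08 to 5.5 (0.859). WT pool 2 was highest for Crabp2 (72.9 CPM against 39.8 to 44.5, gap 0.857), Il10 (0.767 against 0.418 to 0.451, 0.904) and Il24 (9.77 against 0.0375 to 0.561, 0.946). TG pool 2 had 76.1 CPM of Il13 against 5.88 to 17.6 (0.833), and KO pool 2 had 106 CPM of Mir17hg against 123 to 125 (0.880). The intronic share was 8.88% in KO replicate 3 after 48 h of the very weak stimulus, against 12.4% to 12.5% (0.956), and 13.3% in WT replicate 1 after 48 h of the weak stimulus, against 11% to 11.2% (0.923). TG replicate 1 after 24 h of the very weak stimulus held 20.6 M counts against 19.4 to 19.6 M (0.848). The causes were not tested.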

How the results depend on the processing

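Leaving out libraries for the list and exonic minus intronic results, pools, replicates 1 and 2 or 3 and 4 alone, genes that overlap no other gene, and the paired fit of the strengths were tests chosen after the results were seen; the remaining tests in this part were planned. Directions were stable: among the called fold changes of named genes only that of Ifit2 in KO cells turned, from 0.63 with all replicates to -0.10 within replicates 3 and 4. RLE in place of TMM factors left every count of genes within 1.5 times, as did a minimum of 20 intronic counts for the exonic minus intronic effects. Among calls of named genes, each gene counted once per comparison, DESeq2 ended 5 and added 14, RLE factors 3 and 3, no filter 11 and 0, the compared groups alone 17 and 23, the replicate block 0 and 29, pools 95 and 0, pools with the replicate block 28 and 5, replicates 1 and 2 alone 71 and 6, and replicates 3 and 4 alone 89 and 8. Over all fits that left out 1 library 256 such calls ended and 102 were added. Where a value moved, the cause was not tested, except that fits of fewer libraries hold less information. Depth was alike in all groups and limits low-count genes, such as the hairpins; counting intervals cover counting error only. A fit with introns subtracted was not run, since the full table holds no intronic reads.

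Counts of genes depended on how the replicate numbers were used. With the replicate block KO differed from WT in 13 (naive), 350 (very weak, 24 h), 1145 (very weak, 48 h), 436 (weak, 24 h) and 1193 (weak, 48 h) genes and TG in 920 (very weak, 24 h) and 1162 (weak, 24 h), and the KO effect changed on stimulation for 88; the block left the other counts within 1.5 times, including all 4 comparisons of activation and the averages over stimulated states (4048 in KO, 5287 in TG). With the replicate block within state the counts were 19 (naive), 696 (very weak, 24 h), 1878 (very weak, 48 h), 869 (weak, 24 h) and 1964 (weak, 48 h) for KO and 2634 (naive), 1468 (very weak, 24 h), 3340 (very weak, 48 h), 1768 (weak, 24 h) and 2714 (weak, 48 h) for TG, and 361 and 2361 for the change of the KO and TG effects. Lists that passed with the replicate block and not in the same fit without it were, by adjusted p, the naive state in TG naive cells (0.0472), NK and sex-linked genes in stimulated KO cells (0.0412 each), the naive state (0.0419), CDK inhibitors (0.0432), Th1 (0.0432), Th17 (0.0315) and heat shock (0.0475) in stimulated TG cells, and early activation (0.0161), B cell (0.0160) and NK cell genes (0.0498) between the strengths at 24 h. None of these passed with an estimated correlation, at 0.585 (NK and sex-linked in KO, and naive state, CDK inhibitors and Th17 in TG) to 0.900 (naive state in TG naive cells). Whether numbers pair naive libraries was left open.

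In fits of the compared groups alone KO counts were 2 (naive), 80 (very weak, 24 h), 26 (very weak, 48 h) and 74 (weak, 48 h), TG counts 1097 (very weak, 24 h), 1095 (weak, 24 h) and 862 (weak, 48 h), and the effects changed on stimulation for 8 (KO) and 1305 (TG) genes. Within replicates 1 and 2 KO counts were 1 (naive), 9 (very weak, 24 h), 392 (very weak, 48 h), 34 (weak, 24 h) and 367 (weak, 48 h) and 2055 on average, TG counts 385 (naive), 220 (very weak, 24 h), 1156 (very weak, 48 h) and 363 (weak, 24 h), the effects changed for 0 (edgeR, unadjusted p under 0.05 in 1100 genes; DESeq2 was run only on all libraries, with 70) and 372, and 1106 genes moved in opposite directions in KO and TG. Within replicates 3 and 4 KO counts were 2 (naive), 217 (very weak, 48 h), 79 (weak, 24 h) and 246 (weak, 48 h), TG counts 109 (naive), 155 (very weak, 24 h), 604 (very weak, 48 h), 136 (weak, 24 h) and 381 (weak, 48 h) and 2771 on average, the strengths differed in 1 gene at 48 h, the effects changed for 268 and 99, and 1260 genes moved in opposite directions. DESeq2 called 241 (very weak) and 328 genes (weak) in KO at 24 h and 70 for the change of the KO effect, which was 2 without the filter on low counts. Over pools the averages gave 805 genes in KO and 1840 in TG, 491 genes moved in opposite directions (2630, 3972 and 1658 with the replicate block), the exonic minus intronic effect was called for 46 and 31 genes, the interferon list passed in KO (adjusted p = 0.0443, against 0.851 over libraries with an estimated correlation) and the T follicular helper list did not in TG (adjusted p = 0.0621). With WT split by replicates the opposite genes were 1296 (KO against WT 1 and 2) and 836 (KO against WT 3 and 4).

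Paired by replicate block, the strengths in WT cells differed in 414 genes at 24 h and 728 at 48 h. At 24 h further lists then passed, by adjusted p: early activation (0.00953), naive state (0.0429), cell cycle (0.0429), cholesterol (0.0429), interferon response (2.12e-04), Th17 (0.0336), regulatory T cell (0.0429), B cell (3.27e-05), NK cell (0.0429) and heat shock (0.0425) genes. These values use the preset correlation; with an estimated correlation, which was run on unpaired libraries only, each of these lists was at 0.898.

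Exonic minus intronic effects were called for 79 (KO) and 144 (TG) genes with 1 library size for both regions, 578 and 716 with the replicate block by region, 104 and 120 among genes that overlap no other gene, and 401 in KO over pools with the replicate block. They ran from 160 (without KO stimulated replicate 4) to 371 (without KO stimulated replicate 1) in KO and from 223 (without TG stimulated replicate 2) to 403 (without WT stimulated replicate 1) in TG. The site difference turned in intronic counts: -0.00892 in KO (miR-17 -0.0158, miR-18 -0.0232, miR-19 -0.00299 and miR-92 -0.00741) and 0.00512 in TG (miR-17 0.00330, miR-19 0.00844 and miR-92 0.00212), where reads come from outside the mature transcript. In TG the site difference lost its call with an estimated correlation (-0.0653, p = 0.0814), with 7mer-m8 sites included (-0.0392, p = 0.0556) and for exonic minus intronic change (-0.0742, exact p = 0.2). The genes higher after activation lost their call in TG against KO cells with an estimated correlation (0.0973, p = 0.0559) and in the weak 24 h state alone (0.0378, p = 0.0679). For genes higher under the weak stimulus at 48 h camera pointed down in the weak 48 h state alone, at a median of 0.0420.

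Camera calls for gene lists mostly ended with an estimated correlation. This held, with adjusted p in parentheses, for cell cycle and cholesterol (0.969 each) in KO naive cells. In TG naive cells it held for receptors (0.254), cell cycle (0.512), ribosome biogenesis (0.900), cholesterol (0.936) and regulatory T cell (0.0917). In stimulated KO cells it held for published targets (0.103), early activation, CDK inhibitors, ribosome biogenesis, Th1 and Th2 (0.585 each) and glycolysis (0.724). In stimulated TG cells it held for published targets and T follicular helper (0.508 each), ribosome biogenesis (0.752) and interferon response (0.585). In WT activation (weak, 24 h) it held for early activation and CD8 (0.344 each), naive state and myeloid (0.0713 each), receptors (0.0901), ribosome biogenesis and erythroid (0.154 each), glycolysis and cholesterol (0.340 each), interferon response (0.621), TGF-beta signalling and NK cell (0.190 each) and B cell (0.369). Between the strengths at 24 h it held for ribosome biogenesis (0.898).

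Fry asks whether a list moves 1 way and makes no comparison with other genes. It ended calls, with adjusted p in parentheses, for cell cycle (0.788) and cholesterol (0.920) in KO naive cells. It ended those for ribosome biogenesis (0.273) and cholesterol (0.291) in TG naive cells. It ended those for glycolysis (0.0687) in stimulated KO cells. It ended those for ribosome biogenesis (0.948) between the strengths at 24 h. It added calls for T follicular helper (0.0484) in TG naive cells. In stimulated KO cells it added NF-kB (0.0421), NK cell (0.00984) and sex-linked (0.00954). In stimulated TG cells it added naive state (8.11e-04), receptors (1.07e-04), NF-kB (0.00706), CDK inhibitors and regulatory T cell (5.60e-04 each), TGF-beta signalling (0.00689), Th17 (7.97e-04) and myeloid (0.0214). In WT activation (weak, 24 h) it added published targets (1.47e-09), calcineurin and NFAT and NF-kB (5.34e-09 each), PI3K-AKT-mTOR regulators (9.96e-11), the BCL2 family (1.04e-16), CDK inhibitors (7.13e-14), Th17 (0.00478), T follicular helper (0.0129), regulatory T cell (0.00229), innate-like (1.93e-16), sex-linked (0.00589) and heat shock (6.04e-04).

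Single libraries weighed on many counts. In KO naive cells the count was 2 without KO naive replicate 1, 2 without KO naive replicate 4 and 20 without KO naive replicate 2. For KO under the very weak stimulus at 24 h it was 68 without KO very weak 24 h replicate 4, 70 without KO very weak 24 h replicate 3, 85 without WT very weak 24 h replicate 1 and 223 without KO very weak 24 h replicate 1. At 48 h of that stimulus it was 327 without WT very weak 48 h replicate 2, 379 without WT very weak 48 h replicate 4 and 1281 without KO very weak 48 h replicate 3. Under the weak stimulus at 24 h it was 110 without WT weak 24 h replicate 1, 117 without KO weak 24 h replicate 3, 125 without WT weak 24 h replicate 2, 126 without WT weak 24 h replicate 3 and at most 210 without KO weak 24 h replicate 1, and at 48 h 355 without WT weak 48 h replicate 2, 393 without WT weak 48 h replicate 4, 448 without WT weak 48 h replicate 3 and at most 776 without WT weak 48 h replicate 1. The count in TG naive cells was 526 without WT naive replicate 4, 636 without TG naive replicate 4, 646 without WT naive replicate 2 and at most 1195 without TG naive replicate 3. For TG under the very weak stimulus at 24 h it was 269 without TG very weak 24 h replicate 1, 320 without WT very weak 24 h replicate 4, 322 without WT very weak 24 h replicate 3, 328 without WT very weak 24 h replicate 2 and at most 436 without WT very weak 24 h replicate 1. Under the weak stimulus at 24 h it was 292 without TG weak 24 h replicate 2, 330 without TG weak 24 h replicate 1, 345 without WT weak 24 h replicate 4, 393 without WT weak 24 h replicate 3 and at most 672 without TG weak 24 h replicate 4, and at 48 h 812 without TG weak 48 h replicate 2 and at most 1356 without TG weak 48 h replicate 3. The change of the KO effect was called for 1 without KO naive replicate 4, 1 without WT naive replicate 2, 4 without WT naive replicate 4, 7 without KO naive replicate 1, 10 without WT weak 24 h replicate 4, 10 without KO very weak 24 h replicate 2, 11 without WT weak 48 h replicate 4, 12 without KO very weak 24 h replicate 3, 12 without WT very weak 24 h replicate 4, 14 without WT naive replicate 1, 14 without WT very weak 48 h replicate 2, 35 without KO very weak 48 h replicate 3 and 111 without KO naive replicate 2. The change of the TG effect was called for 387 without WT naive replicate 4, 493 without WT naive replicate 2, 543 without TG naive replicate 4 and at most 965 without TG naive replicate 3.

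Leaving out 1 library moved some lists across the threshold; their adjusted p values, lowest and highest, follow. In KO naive cells cell cycle genes were at 4.46e-07 (without WT naive replicate 4) to 0.534 (without WT naive replicate 2). Ribosome biogenesis genes were at 0.0260 (without KO naive replicate 2) to 0.713 (without WT naive replicate 2, and crossed also without WT naive replicate 1). Cholesterol genes were at 5.45e-05 (without WT naive replicate 4) to 0.0583 (without WT naive replicate 2). Regulatory T cell genes were at 0.0268 (without KO naive replicate 4) to 0.804 (without KO naive replicate 2). B cell genes were at 0.0111 (without KO naive replicate 4) to 0.912 (without WT naive replicate 4). Myeloid genes were at 0.00123 (without WT naive replicate 1) to 0.834 (without WT naive replicate 4, and crossed also without KO naive replicate 4). Erythroid genes were at 0.00592 (without WT naive replicate 4) to 0.890 (without WT naive replicate 2, and crossed also without WT naive replicate 1). Heat shock genes were at 0.00123 (without WT naive replicate 1) to 0.564 (without KO naive replicate 4, and crossed also without KO naive replicate 1 and WT naive replicate 4). In TG naive cells naive state genes were at 0.0366 (without WT naive replicate 4) to 0.329 (without WT naive replicate 1, and crossed also without TG naive replicate 3). Receptor genes were at 0.00597 (without TG naive replicate 3) to 0.0557 (without TG naive replicate 4). Cholesterol genes were at 2.47e-04 (without TG naive replicate 4) to 0.196 (without TG naive replicate 3, and crossed also without TG naive replicate 1 and WT naive replicate 1). Myeloid genes were at 0.0412 (without WT naive replicate 1) to 0.842 (without TG naive replicate 1). Erythroid genes were at 0.0458 (without TG naive replicate 2) to 0.810 (without WT naive replicate 2, and crossed also without WT naive replicate 4). Heat shock genes were at 0.00832 (without WT naive replicate 2) to 0.832 (without TG naive replicate 4, and crossed also without WT naive replicate 4). In stimulated KO cells NK cell genes were at 0.0270 (without KO weak 24 h replicate 2) to 0.0920 (without KO weak 24 h replicate 4, and crossed also without KO weak 24 h replicate 1, WT weak 24 h replicate 1, WT weak 24 h replicate 3, KO weak 48 h replicate 1, KO weak 48 h replicate 2, WT weak 48 h replicate 1, KO very weak 24 h replicate 1, KO very weak 24 h replicate 2, WT very weak 24 h replicate 1, WT very weak 24 h replicate 3, KO very weak 48 h replicate 1, KO very weak 48 h replicate 2 and WT very weak 48 h replicate 3). Heat shock genes were at 0.0472 (without WT weak 24 h replicate 3) to 0.179 (without KO weak 24 h replicate 4). In stimulated TG cells naive state genes were at 0.0375 (without WT very weak 24 h replicate 1) to 0.0648 (without TG very weak 24 h replicate 1, and crossed also without WT weak 24 h replicate 1, WT weak 24 h replicate 2, WT weak 24 h replicate 4, TG weak 48 h replicate 1, TG weak 48 h replicate 3, TG weak 48 h replicate 4, WT weak 48 h replicate 1, WT weak 48 h replicate 3, TG very weak 24 h replicate 2, TG very weak 24 h replicate 3, TG very weak 48 h replicate 3 and WT very weak 48 h replicate 3). CDK inhibitor genes were at 0.0375 (without WT very weak 24 h replicate 1) to 0.0794 (without WT very weak 24 h replicate 4, and crossed also without TG weak 24 h replicate 4, WT weak 24 h replicate 1, WT weak 48 h replicate 1 and TG very weak 24 h replicate 4). Th17 genes were at 0.0303 (without TG weak 48 h replicate 3) to 0.0815 (without WT very weak 48 h replicate 4, and crossed also without WT weak 24 h replicate 1, WT weak 24 h replicate 2, WT weak 48 h replicate 1, TG very weak 24 h replicate 3, WT very weak 24 h replicate 2, TG very weak 48 h replicate 3 and WT very weak 48 h replicate 2). T follicular helper genes were at 0.0278 (without WT weak 24 h replicate 3) to 0.0537 (without WT weak 48 h replicate 4, and crossed also without TG weak 24 h replicate 3 and WT very weak 24 h replicate 4). In WT activation (weak, 24 h) CDK inhibitor genes were at 0.0423 (without WT naive replicate 4) to 0.0729 (without WT weak 24 h replicate 1). Between the strengths at 24 h early activation genes were at 0.00623 (without WT weak 24 h replicate 3) to 0.781 (without WT very weak 24 h replicate 3, and crossed also without WT very weak 24 h replicate 2 and WT very weak 24 h replicate 4). Cell cycle genes were at 0.0217 (without WT weak 24 h replicate 3) to 0.957 (without WT very weak 24 h replicate 3). Glycolysis genes were at 0.0336 (without WT weak 24 h replicate 3) to 0.959 (without WT very weak 24 h replicate 3). Cholesterol genes were at 0.00266 (without WT very weak 24 h replicate 1) to 0.796 (without WT weak 24 h replicate 1, and crossed also without WT weak 24 h replicate 3). Th17 genes were at 0.0116 (without WT very weak 24 h replicate 2) to 0.614 (without WT weak 24 h replicate 1). B cell genes were at 9.76e-04 (without WT very weak 24 h replicate 1) to 0.796 (without WT weak 24 h replicate 1, and crossed also without WT weak 24 h replicate 3 and WT weak 24 h replicate 4). NK cell genes were at 0.00687 (without WT very weak 24 h replicate 4) to 0.332 (without WT weak 24 h replicate 4, and crossed also without WT weak 24 h replicate 1, WT weak 24 h replicate 3 and WT very weak 24 h replicate 2). Heat shock genes were at 0.0217 (without WT weak 24 h replicate 3) to 0.924 (without WT very weak 24 h replicate 3). The heat shock list in KO naive cells moved in the other direction without WT naive replicate 1.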

Other observations

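The Cre, genotype and TG batch tests of the interferon genes, the paired fit of the strengths with its gene sets, the pools, and the genes picked by smallest p were chosen after the results were seen; the remaining tests in this part were planned. Genes that rise on activation stood higher in TG than in KO cells, and genes that fall stood lower. The 5042 genes that rose in WT cells after 24 h of the weak stimulus had a median log2 of 0.10 in TG against KO over the stimulated states (camera with the preset correlation between genes, p = 1.57e-07), and the 5573 that fell had -0.15 (2.28e-07). With an estimated correlation the values were p = 0.0559 and 0.0298, and in the weak 24 h state alone p = 0.0679 and 0.0407. Pool scores of the rising set averaged 0.0968 ± 0.0318 in TG and -0.0927 ± 0.0826 in KO (SD, n = 4, exact permutation p = 0.0286), and those of the falling set -0.112 ± 0.0314 and 0.103 ± 0.0976 (exact permutation p = 0.0286), the smallest value possible.

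Some of the genes with the smallest p for exonic beyond intronic change are given here, and what they share was not tested. Cd4 had -1.67 in KO and -1.69 in TG, where both Cre lines held more intronic Cd4 counts. The activation marker Cd69 had 0.83 in KO and -0.37 in TG, and Fam91a1 had -0.43 and 0.67. Jazf1 (1.08 and -0.48), Cast (0.54 and -0.77), Cntln (0.68 and -0.78) and Znfx1 (0.96 in KO) overlap another gene, whose reads the counts do not separate.

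Interferon response genes had a median log2 of 0.486 in KO and -1.23 in TG against WT after stimulation. The prediction for batches of replicates 1 and 2 and of 3 and 4 was met for the KO part, since the median was 0.613 in the former and -0.410 in the latter. In replicates 3 and 4 pool scores did not turn together, at -0.358 and -0.206 in KO against -0.757 and 0.0643 in WT. A batch common to all genotypes would cancel within each set, so this does not show a batch as the cause. For the TG part batches are argued against, since the higher of the values was -0.857. Cre, which KO and TG share, is argued against as the only cause, because the medians had opposite signs and pool scores of TG lay below those of KO (exact permutation p = 0.0286). Other cells in the cultures cannot be told apart. The interferon median in KO did not exceed all marker medians by more than its own spread between KO pools, whose scores ran from -0.358 to 3.19. The marker medians in KO were 0.106 (myeloid, the highest), -0.179 (B) and -0.603 (NK), and in TG -0.432, 0.0818 and -0.442. A candidate explanation that the data leave open is the miR-17~92 genotype: the score of the highest TG pool minus that of the lowest KO pool was -0.574.

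Weak and very weak stimuli differed in 414 genes at 24 h and 728 at 48 h in WT cells once libraries were paired. Chance swaps of the strengths within pairs gave at most 2 and 0 genes, and 1 of 8 swaps, the real one, gave as many at either time, but 8 swaps are too few for a share under 0.05. The cluster may act like a stronger stimulus, in a comparison that joins transgene and deletion: the 166 genes higher at 24 h under the weak stimulus had a median log2 of 0.34 in TG against KO and the 248 lower genes -0.43, a gap of 0.765. Pool scores of both sets differed between TG and KO (exact permutation p = 0.0286 each), and between TG and WT for the lower set (0.0286) but not the higher (0.114), while camera with an estimated correlation gave p = 0.207 and 0.107. For the 48 h sets the medians were 0.09 and -0.27 (exact permutation p = 0.457 and 0.114), so this was seen for the 24 h sets.

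Other splits of the same samples were counted for each comparison, in fits of the compared groups alone. Numbers pair the stimulated libraries of these groups, and only 8 splits, the real one included, part all pairs, too few for a share under 0.05. The counts over all 35 splits ignore pairs, so they are given without a verdict that chance was excluded. For the TG effect 1 of 35 splits, the real one, gave as many genes in every state. It gave 1148 against at most 25 otherwise (naive), and 1097 against 0 and 1623 against 1 (very weak stimulus, 24 h and 48 h). Under the weak stimulus it gave 1095 against 3 and 862 against 0 (24 h and 48 h). The real split also gave the most genes for KO at 24 h, with 80 against 21 (very weak) and 166 against 33 (weak), where the other split set replicates 1 and 2 against 3 and 4. At 48 h chance was not excluded for KO: 2 of 35 splits gave as many, with 26 genes against 571 (very weak) and 74 against 523 (weak). That other split set replicates 1 and 2 against 3 and 4 too. The 7 other splits that part all pairs, as the real one does, gave at most 0 genes in both, whereas the split of 1 and 2 against 3 and 4 keeps pairs together. This points to a structure of the KO and WT samples at 48 h. The same split of TG and WT libraries gave 0 genes at 48 h of either stimulus. In the fit of all 58 libraries, which is of another form, the KO counts were 635 and 691, and 1145 and 1193 with the replicate block. For KO naive cells 2 of 10 splits gave as many (2 against 66), and for the change of the KO effect 2 of 20 (8 against 17), both too few splits for a share under 0.05.

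Averages over stimulated states kept the 4 libraries of a pool together. Again all 35 splits were used, which ignore pairs and allow no verdict that chance was excluded. The real split gave the most genes, 1 of 35, for KO (2890 against 2726, which came from replicates 1 and 2 against 3 and 4), TG (5281 against 2049) and TG against KO (7632 against 3333). Among the 7 other splits that part all pairs, as the real one does, the highest values were 0, 127 and 488. The real split also gave the most genes for the change of the TG effect (1305 against 385, 1 of 35). Its count of splits was corrected after a first outcome was seen. Naive and stimulated libraries are not paired by number, so all 35 splits apply to activation of WT cells. There chance was excluded at 1 of 35, the smallest share possible. The counts were 10127 and 9868 (very weak, 24 h and 48 h) and 10233 and 10005 genes (weak, 24 h and 48 h), each against 0. For the strengths without pairs the real count was 0, which every split reaches, so the splits could not test chance there. Other splits gave up to 438 genes at 24 h and 151 at 48 h. The latter came from replicates 1 and 2 against 3 and 4, which points to a structure of the samples. Exonic minus intronic counts in pools gave 26 against 64 in KO, from replicates 1 and 2 against 3 and 4, and 39 against 134 in TG (2 of 35 each), so chance was not excluded, although the 7 other splits that part all pairs gave at most 0 in both. In the pool fit of all genotypes, which is of another form, the counts were 46 and 31, and 401 and 526 with pools also paired by number.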
